A study of Mus musculus with 10 samples.

How the data were processed

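The deposited series table was used as it was. Per the labels the authors made its log2 expression values with GCRMA and the affy package, whose versions are not given in the sources used here. The values lay between 0.58 and 14.51 with 2 decimals, and no 2 arrays shared more than 1.5% identical values. The scanner files were not used here. RNA was extracted with Trizol and amplified, per the labels, with NuGEN Ovation V2 or Pico WTA V2 reagents.

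Of 22690 probe sets, 64 were AFFX controls, which served only to describe the arrays, and 20380 of the other 22626 carried a single gene symbol. The 691 with several symbols and the 1555 with none were left out. A probe set was kept when it exceeded a log2 value of 4 on at least 2 arrays, which left 14012, and a gene was represented by its kept probe set with the highest mean, which gave 8599 genes. For 3445 genes more than 1 probe set had been kept. Entrez IDs of 20364 probe sets were found in the supplied reference table, and 0 symbols changed.

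Groups were compared with limma 3.58.1 in R 4.3.3. A single linear model held all 10 arrays with a mean per group, contrasts gave the differences, and empirical Bayes moderated the variances (residual degrees of freedom 5, prior 4.1). Adjusted p-values are Benjamini-Hochberg values over the 8599 genes of a comparison, and a gene was called when its adjusted p from limma was under 0.05. For a fold whose lower group lay under 4 on every array, only the fold above that limit is given, as at least so many fold. The full fold is given once an array of the lower group reached 4, also where the mean of the group lay near or under 4. Such a fold rests partly on background values and cannot be ranked against the limited ones. Differences given in log2 units, as under omissions and other alternatives, carry no such limit. Where a group was dim they rest partly on background values. The 7 planned comparisons were the fractions against each other, each fraction against the day 32 sample, the fractions and the day 32 sample against the mean of both iPSC groups, and the iPSC groups against each other. The comparisons, the filter, the gene lists, the tests and the alternatives tied to them were written down before the data were examined. A single iPSC group as reference was among these alternatives and was raised to a comparison of its own after the data were seen. The array classes and the tests of the closing section were also chosen then.

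Named genes follow a rule set before the data were examined. The 4 Yamanaka genes are given in every comparison. For the fractions against each other, the Sox2-positive fraction against iPSC, and the iPSC groups against each other, the 8 largest rises and 8 largest falls are named among genes called with no overlap between the arrays of the groups, and 4 of each in the others. Predicted genes and clone names were passed over. Up to 4 members of a passing list are named in order of p, and members of a list that did not pass in the same order.

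Of 28 fixed gene lists for cell states, lineages and pathways, 27 had at least 4 measured members and were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether the genes of a list rank above or below the other genes, so a list can be placed higher although its median fell with all genes. Each test was repeated with a correlation estimated from the data, and with fry. The directional p of fry asks whether the genes of a list move on balance in a single direction and its mixed p whether they move in either direction, and neither compares them with other genes.

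In a self-test on simulated arrays, drawn independently around the mean of each gene with its moderated spread, 200 of 8599 genes were given known changes. Limma recovered 4 of 67 genes changed by 1 log2 unit (6%), 57 of 67 changed by 2 (85.1%) and 66 of 66 changed by 4 (100%), with 10 false calls. A list of 17 genes raised by 1 was found by camera (adjusted p = 3.02e-18), as was 1 of the 26 other lists, of which some share members with it. Simulated genes are independent of each other, so this test does not measure how camera fares when they are not. A gene not called may therefore still have changed by 2-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.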

Results

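The series holds 10 single-channel Affymetrix arrays of mouse cells in 5 groups of 2 arrays each. Established induced pluripotent stem cells (iPSC) had been grown either in 2i (inhibitors of the ERK pathway and of GSK3) with serum, or in co-culture with mouse embryonic fibroblasts (MEFs), and the labels do not say whether MEFs were removed before the RNA was taken. Secondary MEFs, which carry inducible copies of the Yamanaka factors Pou5f1, Sox2, Klf4 and Myc, had expressed these factors for 32 days and gave the other 3 groups. These were a day 32 sample for which the labels name no fraction, a Sox2-positive fraction and a Sox2-negative fraction. The labels tie the series to RNA FACS, the sorting of cells by the RNA they hold. Of the probe sets on the array 14012 passed the filter and gave 8599 genes, and all values below are deposited log2 units. The labels state n = 2 per group without saying whether replicates were separate cultures, so the p-values measure only the spread between these samples, pooled over all 5 groups. The median absolute difference between replicates was 0.39 in the Sox2-positive and 0.41 in the Sox2-negative fraction. It was 0.26 in iPSC in 2i and serum, 0.25 in iPSC with MEFs and 0.3 in the day 32 sample. The pooled spread may therefore be too small for the comparison of the fractions. With 2 arrays against 2 an exact two-sided permutation p cannot go below 0.33. The number of arrays limits the precision.

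The arrays formed 2 classes by the control probe sets for 18S ribosomal RNA. The 18S value at the 3' end averaged 12.75 ± 0.70 (SD, n = 6 arrays) for iPSC with MEFs and the 2 sorted fractions, and 5.99 ± 0.55 (n = 4 arrays) for iPSC in 2i and serum and the day 32 samples. The gap between the 3' and 5' probe sets of Actb, which widens when the 5' end is copied poorly, averaged 0.44 in the class with high 18S and 3.21 in the class with low 18S. The gap of the transferrin receptor control parted the classes likewise (0.48 and 3.14). That of Gapdh did not, at 1.80 (range 1.03 to 3.18) and 1.42 (0.84 to 2.25). The median of all values was 4.31 and 5.32 in the same order. The labels name 2 amplification kits and do not say which sample had which. Class and group cannot be told apart in comparisons of a sorted fraction with the day 32 sample, or of the 2 iPSC groups with each other. The planned reference, the mean of the 2 iPSC groups, mixes the classes. The fractions against each other, each fraction against iPSC with MEFs, and the day 32 sample against iPSC in 2i and serum stay inside a class. A single iPSC group as reference had been planned as an alternative, and was raised to a comparison of its own, given first below, after the data were seen. Inside the class with high 18S the iPSC with MEFs still stood apart, with upper quartiles of 7.35 and 7.37 against 6.87 to 6.91 on the sorted arrays. Its 3' to 5' gaps were 1.12 and 1.08 for Actb, against 0.05 to 0.21, and 3.18 and 2.53 for Gapdh, against 1.03 to 1.56. Whether all arrays were normalized jointly is not stated in the sources used here.

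**Figure D1:**
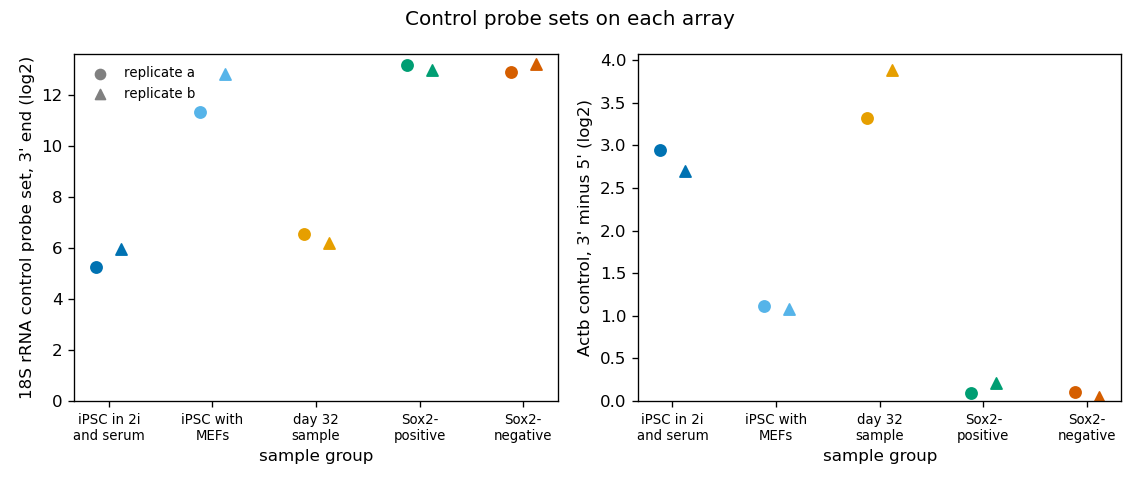
18S ribosomal RNA (3' probe set) and the difference between the 3' and 5' probe sets of Actb on each of the 10 arrays, deposited log2 values. Arrays are grouped by sample group, n = 2 per group.

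Sox2-positive and Sox2-negative cells of day 32 differed most in pluripotency genes. Sox2 itself read 9.96 ± 0.70 (SD, n = 2) in the positive and 4.29 ± 0.23 in the negative fraction, a difference of 5.66 (SE 0.39) or 50.7-fold (limma adjusted p = 2.61e-04). The fractions are named by Sox2, so this difference reflects the sort and tests nothing beyond it. Dppa5a, a marker of undifferentiated cells, was 164-fold higher in the positive fraction (12.29 ± 0.05 against 4.93 ± 1.70, adjusted p = 4.74e-04), and the fatty acid carrier Fabp3 was 116-fold higher (adjusted p = 3.41e-04). The naive pluripotency gene Zfp42 was at least 50.4-fold higher (adjusted p = 2.61e-04), Dppa2 at least 66.7-fold, Trap1a at least 41.4-fold, Morc1 at least 29.1-fold and Zfp936 at least 15.8-fold. Rex2 was 91.1-fold higher (adjusted p = 0.0121), with a wide spread in the negative fraction (3.62 ± 3.30). In the other direction the fat cell gene Fabp4 read 5.29 ± 0.21 in the positive and 11.70 ± 0.64 in the negative fraction, 85.3-fold lower (adjusted p = 7.96e-04). The stress keratin Krt6b was at least 52.9-fold lower in the positive fraction (adjusted p = 0.0023). The cytokine gene Csf1 was at least 25.8-fold lower, Mgst1 at least 23.2-fold, the matrix genes Efemp1 and Thbs1 at least 21.6-fold and 14.5-fold, Tnfaip2 38.9-fold, and Cyp1b1 at least 16-fold (adjusted p = 0.0214). Of 8599 genes limma called 1076 at an adjusted p under 0.05, 590 higher and 486 lower in the positive fraction, and the all-gene median difference was -0.02. Every named gene that passed here had both arrays of the higher fraction above both arrays of the lower. The naming rule had required this of the largest rises and falls, so for them it is no added support. The count fell to 404 without replicate b of the Sox2-positive fraction, to 369 with array weights and to 323 with the compared arrays alone. Rex2 lost its call without Sox2-positive replicate b (adjusted p = 0.0684) and with the compared arrays alone (0.0814), and its difference of 6.51 became 4.18 without Sox2-negative replicate a, while Cyp1b1 lost it on leaving out any of the 4 arrays (0.0590 to 0.0842) and with array weights (0.1126).

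The pluripotency lists were higher as groups in the Sox2-positive fraction. In the naive pluripotency list, 15 genes with a median difference of 4.69, 12 were called higher and 0 lower, among them Zfp42, Dppa5a, the transcription factor Tbx3 (36.8-fold, limma adjusted p = 3.41e-04) and the adhesion gene Pecam1 (at least 9.09-fold). Adjusted over the list alone, 13 were higher and 0 lower, and camera gave an adjusted p = 1.43e-14, against an adjusted p = 0.34 with an estimated correlation. The general pluripotency list (17 genes, median 3.88) had 15 called higher and 0 lower, such as Dppa2, Sox2, the F-box gene Fbxo15 (6.66-fold) and the signalling ligand Gdf3 (29.9-fold). Over this list alone 16 were higher and 0 lower, camera adjusted p = 1.17e-14 and adjusted p = 0.341 with an estimated correlation. Sox2 was counted in this list, although the fractions are named by it. In the list of germ cell and 2-cell stage genes (9 genes, median 3.57), 7 were called higher and 0 lower, such as the transposon repressor Tex19.1 (36.8-fold, adjusted p = 0.0062), the meiosis genes Sycp3 and Hormad1 (at least 8.34-fold and 5.62-fold) and Dazl (at least 6.36-fold). Adjusted over that list alone all 9 were higher, with a camera adjusted p = 1.35e-06 and an adjusted p = 0.384 with an estimated correlation. The list of DNA methylation and chromatin genes (14 genes, median 1.28) had 7 called higher and 0 lower, such as the dioxygenase Tet1 (19.2-fold, 9.61 ± 0.52 against 5.35 ± 0.27), the methyltransferase genes Dnmt3b (11.3-fold, adjusted p = 0.0062) and Dnmt3l (at least 17.4-fold), and Cbx7 (7.04-fold). Over this list alone 9 were higher and 0 lower, camera adjusted p = 1.35e-06 and adjusted p = 0.384 with an estimated correlation. With dim groups held at their bound the median of the naive list was 3.33 and that of the germ cell list 1.65. Dazl lost its call without Sox2-positive replicate b (adjusted p = 0.0824) or Sox2-negative replicate a (0.0600), and Dnmt3b with the compared arrays alone (0.0552). No list in any comparison passed with an estimated correlation, so every camera result here rests on the preset correlation between genes.

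Part of the epithelial genes were higher and part of the fibroblast genes lower in the Sox2-positive fraction. E-cadherin (Cdh1) was 15.5-fold higher (10.93 ± 0.69 against 6.97 ± 0.13, n = 2, limma adjusted p = 5.83e-04), the tight junction genes Cldn6 8.94-fold and Cldn4 at least 6.06-fold, and Spint1 13.6-fold. The epithelial list (19 genes, median 1.26) had 7 called higher and 0 lower, and 11 higher and 3 lower when adjusted over the list alone. Its camera adjusted p was 2.71e-04, with an adjusted p = 0.384 with an estimated correlation. In the fibroblast and mesenchymal list (24 genes, median -1.18), 5 genes were called lower, such as S100a4 (at least 7.41-fold), the collagen gene Col6a1 (at least 3.61-fold) and the collagen crosslinker Loxl1 (at least 2.75-fold). The fibronectin gene Fn1 went the other way, 10.8-fold higher (11.00 ± 0.13 against 7.56 ± 0.67, adjusted p = 0.0013). Adjusted over the list alone 1 was higher and 8 lower, and camera gave an adjusted p = 2.71e-04 and an adjusted p = 0.341 with an estimated correlation. The primed epiblast list (9 genes, median 1.39) had 4 called higher, namely Dnmt3b, the Nodal antagonist Lefty1 (at least 4.68-fold, adjusted p = 0.0127), the POU factor Pou3f1 (at least 3.03-fold, 0.0195) and Nodal (4.39-fold, 0.0368). Over this list alone 6 were higher and 0 lower, camera adjusted p = 0.0017 and adjusted p = 0.492 with an estimated correlation. In the glycolysis list (15 genes, median 0.40) 3 were called higher and 0 lower, namely Pfkp (8.22-fold, 9.30 ± 0.12 against 6.25 ± 0.06), Pfkl (2.53-fold, adjusted p = 0.0307) and Aldoa (1.96-fold, 0.0457). Over this list alone 4 were higher and 0 lower, camera adjusted p = 0.0090 and adjusted p = 0.524 with an estimated correlation. Bounds lowered the medians of the epithelial, fibroblast and primed lists to 0.39, -0.38 and 0.87. The calls for Pfkl, Aldoa and Nodal were the least firm. Without Sox2-positive replicate a or b, or Sox2-negative replicate a or b, the adjusted p of Pfkl was 0.0531, 0.1263, 0.0727 and 0.0883, and that of Aldoa 0.1044, 0.1292, 0.1245 and 0.0870. Nodal lost its call without Sox2-positive replicate a (0.0548) or b (0.1637) or Sox2-negative replicate a (0.1560), Pou3f1 without Sox2-positive replicate b (0.1053) or Sox2-negative replicate a (0.0779), Lefty1 without Sox2-positive replicate b (0.0757), and Loxl1 with the compared arrays alone (0.0557).

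The remaining lists did not pass between the fractions. The trophoblast list had a median of 1.39 (camera adjusted p = 0.0575), with Ascl2 called at least 4.5-fold higher in the positive fraction (limma adjusted p = 0.0078). The smooth muscle list had a median of -1.06 (0.0764), and its Ccn1 was 6.39-fold lower (0.0017). The cell cycle list had a median of 0.30 (0.0936), with Bub1 and Top2a called 3.26-fold and 2.65-fold higher. The median was -0.56 for p53 targets (0.4146), -0.51 for the ERK response (0.2772), 0.16 for ribosomal proteins (0.4440), 0.08 for oxidative phosphorylation (0.2717) and 0.25 for interferon genes (0.8850). Imprinted genes (median 0.09, mean -0.06) and Wnt targets (median -0.07, mean 0.14) had medians and means of opposite sign (0.9638 for each list).

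**Figure D2:**
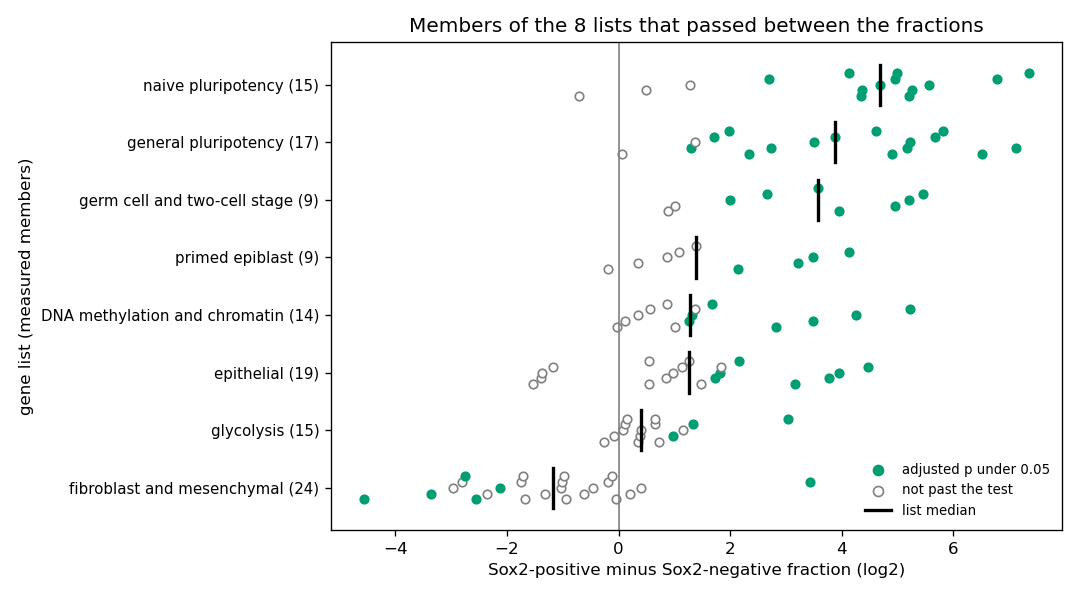
Differences between the Sox2-positive and the Sox2-negative fraction for the genes of the 8 lists that passed in this comparison, log2 units. Each point is a gene, filled where its adjusted p was under 0.05, and the black bar is the median of the list.

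Of the Yamanaka genes only Sox2, by which the fractions are named, was called different between the fractions. Pou5f1 read 10.65 ± 0.38 in the positive and 10.59 ± 0.74 in the negative fraction (n = 2 each, difference 0.06, limma adjusted p = 0.9277), beside 10.75 ± 0.04 in iPSC in 2i and serum, 9.63 ± 0.17 in iPSC with MEFs and 10.70 ± 0.06 in the day 32 sample. Myc read 7.97 ± 1.97 and 9.43 ± 0.62 (difference -1.46, adjusted p = 0.3493). Klf4 read 9.91 ± 0.29 and 10.62 ± 0.33 (difference -0.71, adjusted p = 0.4348). The list of the 4 genes had a median of -0.32 and a mean of 0.89, and camera put it higher without passing (adjusted p = 0.5235). The other probe set of Klf4 on the array gave 8.88 ± 0.56 in the positive and 4.77 ± 0.66 in the negative fraction, a difference of 4.11 (adjusted p = 0.0040 over the 14012 probe sets, where the used one had 0.4417). The mean of the probe sets turned the Klf4 difference to 1.70. The gap between the probe sets was 0.47 ± 0.07 in iPSC in 2i and serum, 0.23 ± 0.02 in iPSC with MEFs and 0.19 ± 0.02 in the day 32 sample, but -1.03 ± 0.85 and -5.85 ± 0.34 in the positive and the negative fraction. The Pou5f1 difference turned to -0.46 without Sox2-negative replicate a and to -0.20 without Sox2-positive replicate a.

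**Figure D3:**
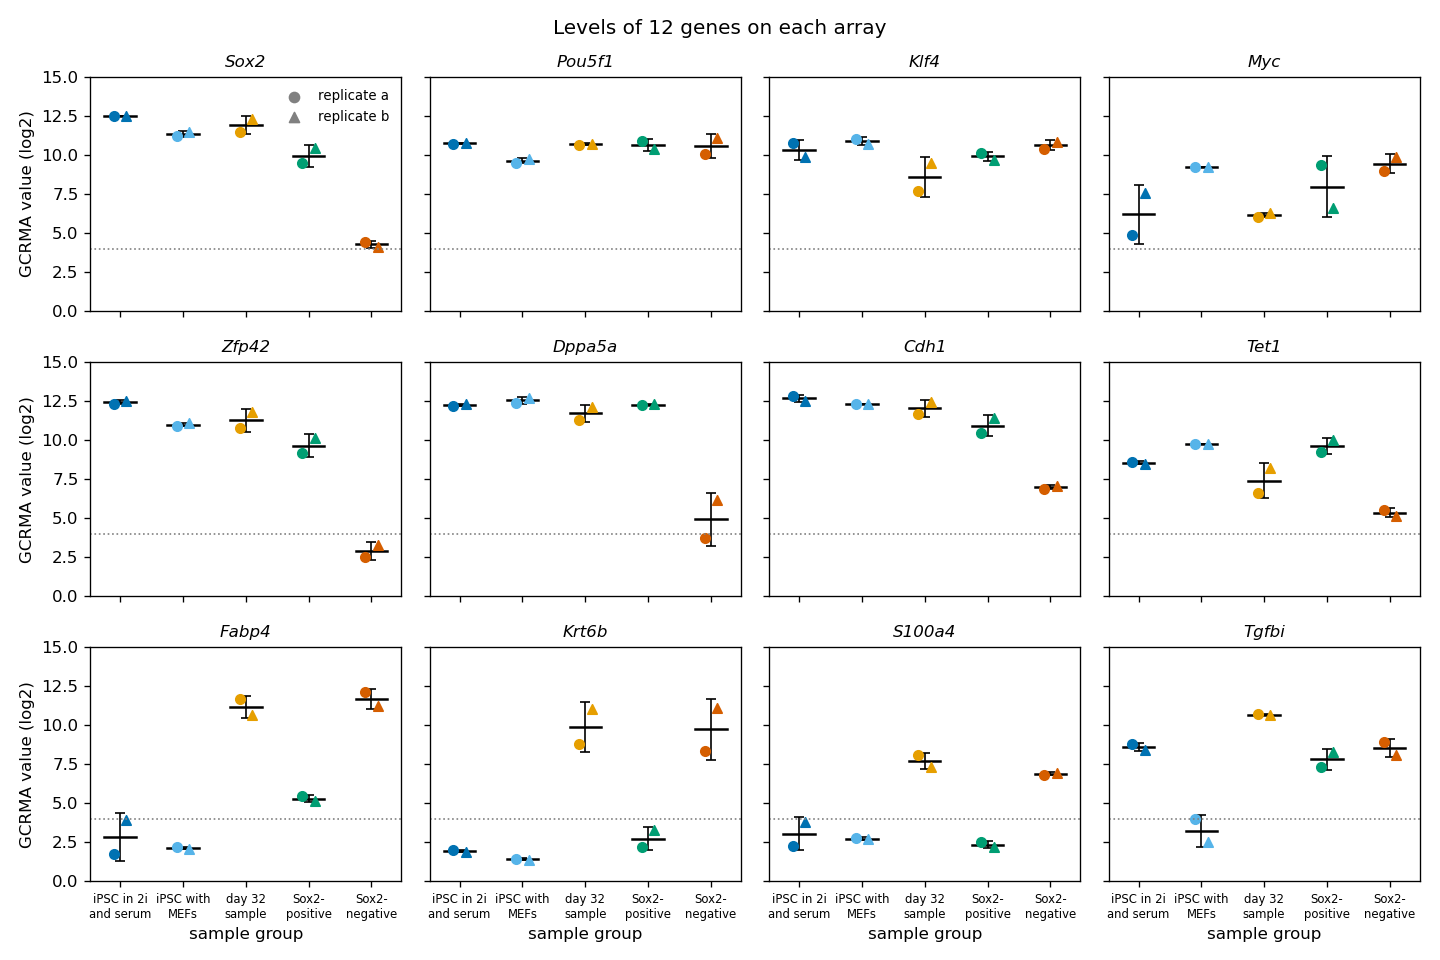
Deposited log2 values of 12 genes on all arrays. Circles are replicate a, triangles replicate b, bars the mean ± SD (n = 2), and the dotted line marks the filter value of 4.

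Sox2-positive cells had higher Slc11a1 and Tgfbi and lower Ina and Sp5 than iPSC with MEFs. The metal transporter gene Slc11a1 was 55.3-fold higher in the Sox2-positive fraction (limma adjusted p = 0.0013), the matrix gene Tgfbi at least 14-fold (9.98e-04), Fetub 17.4-fold (0.0040) and the G protein gene Gnaq 6.89-fold (8.94e-04). Pax3, a neural crest factor, was at least 6.68-fold higher (0.0095), and Ces2g, Wnt5a, Srgn and Foxd1 were also called higher. Of the iPSC groups only iPSC with MEFs was low in Slc11a1 and Tgfbi. In iPSC in 2i and serum they read 8.63 ± 0.42 and 8.61 ± 0.28, against 9.80 ± 0.88 and 7.80 ± 0.66 in the Sox2-positive fraction, across the array classes. Pax3, Ces2g, Wnt5a and Foxd1 were under the filter value of 4 in both iPSC groups. Lower than in iPSC with MEFs were the neurofilament genes Ina and Nefh (at least 15.9-fold and 8.88-fold), the Wnt target Sp5 (at least 8-fold, adjusted p = 8.47e-04), Ntn1 (21.9-fold), Bmerb1 (20.6-fold), the signalling gene Bmp4 (18.9-fold), and the mesenchymal genes Col1a1 (at least 11-fold, 0.0042) and Acta2 (at least 19.9-fold). Sox2 was 1.42 log2 units lower (adjusted p = 0.0208), and Pou5f1, Klf4 and Myc differed by 1.02 (0.0517), -0.97 (0.1967) and -1.28 (0.3234). In all 3088 genes were called, 527 higher and 2561 lower, around an all-gene median of -0.45. Quantile normalization left 1594, 626 higher and 968 lower, with an all-gene median of -0.11, and Sox2 at -0.55 (adjusted p = 0.3318). Median centring gave 2168, 1009 higher and 1159 lower, and Sox2 at -0.96 (0.0883). The count was 1192 and 1517 without replicate a or b of iPSC with MEFs and 1822 without Sox2-positive replicate a. Sox2 lost its call without each of these arrays (0.0771, 0.1107 and 0.1248), as did Ces2g (0.0772, 0.0746 and 0.0693), Srgn (0.0717, 0.0785 and 0.0859), Wnt5a (0.1058, 0.0825 and 0.1276) and Foxd1 (0.0920, 0.1007 and 0.0655). Acta2 lost it without any of the 4 arrays (0.0748 to 0.1154). Pax3 lost it without iPSC with MEFs replicate a (0.0665), and its difference of 4.46 became 2.61 without Sox2-positive replicate a. Myc turned to 0.12 without Sox2-positive replicate b.

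Of the lists, only endoderm passed between Sox2-positive cells and iPSC with MEFs. The list (11 genes) had a median of 1.12, or 1.57 above the all-gene median, with 6 called higher and 0 lower, such as the basement membrane collagen Col4a2 (13.1-fold, limma adjusted p = 0.0063) and the endocytic receptor Cubn (at least 1.05-fold, 0.0076). Adjusted over the list alone 7 were higher and 1 lower, and camera gave an adjusted p = 6.50e-04 and an adjusted p = 0.623 with an estimated correlation. Dim groups held at their bound left a median of 0.01, and the called members Hnf4a and Gata4 were below the filter value of 4 on every array of both groups. Without replicate b of iPSC with MEFs, Col4a2, Cubn, Hnf4a and Gata4 lost their calls (0.0524, 0.0532, 0.0941 and 0.0937), Gata4 did so without any of the 4 arrays (0.0577 to 0.0937), and Hnf4a also without replicate a of iPSC with MEFs (0.0869) or Sox2-positive replicate a (0.1153). The naive pluripotency list did not pass (median -0.98, 2 higher and 7 lower, adjusted p = 0.670), with Pecam1 5.01-fold higher and Dppa3 7.95-fold lower in the positive fraction. The general pluripotency list (median -0.52, 0 higher and 5 lower, adjusted p = 0.972) did not pass either, and its Sall4 was 2.79-fold lower (limma adjusted p = 0.0186) by the probe set used, with another kept probe set in the opposite direction. The cell cycle list had a median of -0.90 with 0 higher and 10 lower (adjusted p = 0.1975), led by cyclin E1 (Ccne1), 8.25-fold lower.

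Against the planned reference, the mean of both iPSC groups, Slc11a1, Pax3, Ces2g, Wnt5a and Foxd1 were again among the largest rises of the Sox2-positive fraction, and Nefh and Ina among the largest falls. Gnaq (13.5-fold, limma adjusted p = 9.38e-05), Slc11a1 (11.2-fold), Slc4a4 (at least 4.33-fold), Pax3 (at least 6.68-fold), Ces2g (at least 5.12-fold), Foxd1 (at least 4.64-fold), Wnt5a (at least 4.32-fold) and the cyclin gene Ccnd2 (9.40-fold) were the largest rises. The largest falls were Bcl10 (22.0-fold), Ajuba (18.6-fold), Aard (16.9-fold), Ets2 and Errfi1 (15.8-fold each), Nefh (at least 15-fold), Ina (at least 11.9-fold) and Ttc30a1 (at least 5.62-fold). All of these except Ccnd2 (1.58, adjusted p = 0.2383) were also called against iPSC with MEFs. Several were not particular to the positive fraction. Gnaq read 7.53 in the positive and 7.62 in the negative fraction (3.20 at day 32), Ets2 4.05 and 4.47 (8.98), and Errfi1 5.22 and 4.76 (10.43). Others differed between the fractions, such as Slc11a1 (9.80 and 3.39) and Aard (5.97 and 1.41). Changes shared by both fractions cannot be told apart from effects of sorting or processing. Sox2 was 1.98 lower (0.0010), and Pou5f1, Klf4 and Myc differed by 0.46 (0.2189), -0.70 (0.2256) and 0.25 (0.8089). The endoderm list passed (median 0.30, or 1.24 above the all-gene median, 2 higher and 1 lower, camera adjusted p = 0.0012), with 1 higher and 0 lower over the list alone and an adjusted p = 0.767 with an estimated correlation. Of all genes 5364 were called, 388 higher and 4976 lower around an all-gene median of -0.94. After quantile normalization there were 2970, 1036 higher and 1934 lower, after median centring 2964, 1764 higher and 1200 lower, and with iPSC with MEFs alone as reference 3088. Without Sox2-positive replicate a, Ces2g (2.04, adjusted p = 0.0790), Wnt5a (2.36, 0.0743), Ccnd2 (1.78, 0.1137) and Foxd1 (1.23, 0.0934) lost their calls and Pax3 moved from 4.19 to 2.34, and Slc11a1 lost its call with iPSC in 2i and serum alone as reference. Sox2 was no longer called after median centring. The Klf4 difference turned to 0.29 after quantile normalization and 0.38 after median centring, that of Pou5f1 to -0.10 with iPSC in 2i and serum alone, and that of Myc to -1.28 with iPSC with MEFs alone, to -0.42 without iPSC in 2i and serum replicate a and to -1.15 without Sox2-positive replicate a.

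Sox2-negative cells had lower Dppa2 and Zfp42 and higher Fabp4, Pax3 and Krt6b than iPSC with MEFs. Fabp4 was at least 208-fold higher in the Sox2-negative fraction than in iPSC with MEFs (limma adjusted p = 9.85e-05), Pax3 at least 91.1-fold, the esterase gene Ces2g at least 64-fold and Krt6b at least 52.9-fold. Dppa2 was at least 228-fold lower, Zfp42 at least 127-fold, Pla2g1b at least 112-fold, the germline gene Dppa3 at least 79.9-fold and Trap1a at least 78-fold. Sox2 was 135-fold lower (adjusted p = 8.89e-05), and Pou5f1, Klf4 and Myc differed by 0.96 (0.0525), -0.27 (0.7094) and 0.18 (0.8899). The other probe set of Klf4 read 4.77 ± 0.66 in the Sox2-negative fraction and 11.12 ± 0.27 in iPSC with MEFs (n = 2 each), so the Klf4 probe sets disagreed. Limma called 4087 genes, 1028 higher and 3059 lower, around an all-gene median of -0.50. Quantile normalization gave 3075, 1272 higher and 1803 lower, and median centring 3513, 1633 higher and 1880 lower. The count was 2523 and 2678 without replicate a or b of iPSC with MEFs. Klf4 turned to 0.48 after quantile normalization and 0.17 after median centring, and Myc to -0.25 without Sox2-negative replicate b.

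As groups, pluripotency, methylation, cell cycle and glycolysis genes were lower in Sox2-negative cells than in iPSC with MEFs, and fibroblast, endoderm and BMP or TGFb genes higher. The naive list had a median of -5.43 (0 higher and 14 lower, camera adjusted p = 1.80e-06), with Tbx3 43.1-fold lower and Tfcp2l1 at least 22.6-fold lower. The general pluripotency list had a median of -5.02 (0 higher and 16 lower, 1.66e-05), with Gdf3 85.0-fold and Fbxo15 9.82-fold lower. In the methylation list (median -1.75, 0 higher and 11 lower, 3.29e-04) Dnmt3b was 120-fold lower (limma adjusted p = 1.05e-04), Dnmt3l at least 78-fold, Tet1 21.5-fold and the Polycomb gene Eed 9.61-fold. In the cell cycle list (median -1.12, 0 higher and 14 lower, 0.0153) Ccne1 was 11.3-fold lower, Top2a 4.10-fold, and the replication genes Mcm3 and Mcm5 3.22-fold and 3.28-fold. The glycolysis list (median -1.09, 1 higher and 12 lower, 0.0335) included Pfkp, 7.29-fold lower, and Pfkl, 3.86-fold lower. The fibroblast list (median 0.71, 8 higher and 3 lower, 0.0015) ran both ways, with S100a4 at least 7.41-fold and Loxl1 at least 2.75-fold higher, but Fn1 17.1-fold and Col1a2 at least 2.69-fold lower. In the endoderm list (median 0.90, 3 higher and 1 lower, 0.0090) Col4a2 and Col4a1 were 23.4-fold and 15.7-fold higher. In the BMP and TGFb list (median 0.82, 4 higher and 2 lower, 0.0170) Tgfbi was at least 22.8-fold and Id2 18.8-fold higher, while Smad7 and Bambi were 4.86-fold and 4.30-fold lower. Adjusted over each list alone the calls were 14 lower for naive, 16 lower and 1 higher for general, 14 lower for methylation, 15 lower for cell cycle, 12 lower and 1 higher for glycolysis, 8 higher and 3 lower for fibroblast, 3 higher for endoderm, and 5 higher and 2 lower for BMP and TGFb. With an estimated correlation none passed, with adjusted p = 0.541 to 0.632.

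Against the planned iPSC mean, Fabp4, Pax3 and Krt6b were again among the largest rises of the Sox2-negative fraction and Dppa2 and Pla2g1b among the largest falls. Krtdap was 233-fold higher (limma adjusted p = 2.11e-05), Fabp4 at least 208-fold, Pax3 at least 91.1-fold and Krt6b at least 52.9-fold, and Zfp42 was at least 210-fold lower, Dppa2 at least 187-fold, Pla2g1b at least 134-fold and Aard at least 66.4-fold. Sox2 was 200-fold lower (1.15e-05), and Pou5f1, Klf4 and Myc differed by 0.40 (0.2782), 0.01 (0.9860) and 1.71 (0.0932). The naive (median -5.94, 0 higher and 14 lower, camera adjusted p = 2.51e-04), general pluripotency (-4.99, 0 and 16, 0.0014) and methylation lists (-1.83, 0 and 13, 0.0116) were lower. The fibroblast list (0.42, 7 and 5, 2.51e-04), the ERK response (0.32, 5 and 4, 0.0039, with Fosl1 21.9-fold and Phlda1 8.63-fold higher), endoderm (0.22, 3 and 2, 0.0173), BMP and TGFb (0.33, 3 and 3, 0.0173) and neural genes (0.0173, with Fabp7 at least 2.19-fold higher) were placed higher. The neural list had a median of -0.32 but a mean of 0.46, with 4 higher and 4 lower. Neither the ERK response nor the neural list passed against iPSC with MEFs alone. Their calls thus depend on including iPSC in 2i and serum, which had an ERK pathway inhibitor and belong to the other array class. The adjusted p with an estimated correlation was 0.410 for the fibroblast and ERK lists and 0.561 for the others. Adjusted over each list alone, higher and lower calls were 0 and 14 for naive, 0 and 16 for general, 0 and 14 for methylation, 6 and 5 for fibroblast, 6 and 5 for ERK, 3 and 1 for endoderm, 3 and 3 for BMP and TGFb and 4 and 4 for neural genes. In all 5901 genes were called, 777 higher and 5124 lower around an all-gene median of -0.97, and 4274 after quantile normalization, 1608 higher and 2666 lower. Median centring gave 4208, 2331 higher and 1877 lower. Klf4 turned to -3.09 with the mean of its probe sets, where it passed (adjusted p = 5.19e-04), to -0.27 with iPSC with MEFs alone, and to -0.21, -0.08 and -0.22 without replicate b of iPSC in 2i and serum, of iPSC with MEFs or of the Sox2-negative fraction. Pou5f1 turned to -0.16 with iPSC in 2i and serum alone and to -0.13 without Sox2-negative replicate b.

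The day 32 sample had higher Fabp4, Krtdap, Zic1 and Krt6b than iPSC in 2i and serum. Fabp4 was at least 145-fold higher at day 32 (11.18 ± 0.71 against 2.81 ± 1.56, n = 2, limma adjusted p = 9.43e-04), the skin gene Krtdap 101-fold (9.43e-04), the neural crest factor Zic1 at least 85.3-fold (0.0012) and Krt6b at least 59.5-fold (0.0024). Krtdap averaged 3.63 in iPSC in 2i and serum, so its fold rests partly on background. Lower were Ttn (31.1-fold, 0.0031), Calcoco2 (24.8-fold, 0.0018), Mcf2 (11.9-fold, 0.0091) and Zfp936 (10.7-fold, 0.0135). The Yamanaka genes were not called, with differences of -0.05 for Pou5f1 (0.9500), -0.58 for Sox2 (0.3978), -1.76 for Klf4 (0.0891) and -0.05 for Myc (0.9816). Limma called 665 genes, 450 higher and 215 lower, around an all-gene median of -0.10. With the compared arrays alone 262 were called, 221 higher and 41 lower, and 259, 208 and 127 without iPSC in 2i and serum replicate a, its replicate b, or day 32 replicate a. Mcf2 lost its call without iPSC in 2i and serum replicate a (0.0579) and with the compared arrays alone (0.0691), and Zfp936 without iPSC in 2i and serum replicate b (0.0930) and with the compared arrays alone (0.0841). Pou5f1 turned to 0.09 after quantile normalization, and Myc to 1.29 without iPSC in 2i and serum replicate b and to 0.05 without day 32 replicate a.

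Fibroblast and immediate early genes had the smallest camera p among the lists higher at day 32 than in iPSC in 2i and serum. This reference had been grown with an inhibitor of the ERK pathway. For ERK response and immediate early genes, a rise at day 32 therefore cannot be told apart from a low level in the reference. Neither of these lists passed against the planned iPSC mean. The fibroblast list (24 genes, median 1.61) had 7 called higher and 0 lower, such as S100a4 (at least 13-fold, limma adjusted p = 0.0017), Col6a1 (at least 12.4-fold) and the mesenchymal factor Twist2 (at least 3.89-fold). Over this list alone 11 were higher and 0 lower, camera adjusted p = 7.03e-07 and adjusted p = 0.218 with an estimated correlation. The list of immediate early and heat shock genes (17 genes, median 1.75) had 8 called higher and 0 lower, such as Egr2 (at least 29.2-fold), Fos (16.9-fold, adjusted p = 0.0045) and the chaperone gene Hspa1a (at least 6.13-fold). Over this list alone 11 were higher and 2 lower, camera adjusted p = 5.52e-05 and adjusted p = 0.218 with an estimated correlation. Endoderm (median 1.47, 4 higher and 0 lower, with Dab2 13.4-fold and Cubn at least 4.91-fold higher, camera adjusted p = 5.46e-04), ERK response (0.76, 5 and 1, 0.0020, with Fosl1 at least 10.4-fold higher), BMP and TGFb (1.08, 3 and 1, 0.0116), p53 targets (0.53, 3 and 0, 0.0202) and keratinocyte genes (1.83, 2 and 0, 0.0321) also passed as higher. The naive (-1.17, 0 and 2, 1.12e-04), general pluripotency (-0.80, 0 and 2, 0.0023), methylation (-0.55, 0 and 0, 0.0202) and cell cycle lists (-0.54, 0 and 1, 0.0290) passed as lower. Adjusted over each list alone, higher and lower calls were 6 and 0 for endoderm, 7 and 1 for ERK, 8 and 1 for BMP and TGFb, 3 and 0 for p53, 4 and 0 for keratinocyte, 0 and 9 for naive, 0 and 2 for general, 0 and 0 for methylation and 0 and 1 for cell cycle. With an estimated correlation the adjusted p of these lists lay between 0.218 and 0.507. Without day 32 replicate a, every called member of the BMP and TGFb, p53, keratinocyte, naive, general and cell cycle lists lost its call.

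Set against the planned iPSC mean, Fabp4, Zic1 and Krt6b were again among the largest rises of the day 32 sample, together with Ces2g (at least 48-fold). Calcoco2 was 20.2-fold lower (limma adjusted p = 2.59e-04), Myo10 15.8-fold, Zfp936 14.4-fold and the ERK-responsive gene Etv5 12.1-fold. Inside the class with low 18S, Myo10 was 1.12 lower without passing (0.0749) and Etv5 1.25 lower (0.0302). Klf4 was 2.03 lower (adjusted p = 0.0097), and Pou5f1, Sox2 and Myc differed by 0.51 (0.2156), -0.01 (0.9756) and -1.58 (0.1568). The lists passing as lower, each with its median, higher and lower calls and camera adjusted p, were naive (-0.57, 0 and 4, 7.02e-05), general pluripotency (-0.71, 0 and 2, 7.08e-04), methylation (-0.51, 0 and 3, 0.0011), ribosomal (-0.44, 0 and 3, 0.0016), cell cycle (-0.28, 1 and 7, 0.0039), primed epiblast (-0.88, 0 and 1, 0.0074), glycolysis (-0.39, 1 and 1, 0.0197) and Wnt targets (-1.01, 0 and 4, 0.0277). Those passing as higher were endoderm (1.92, 8 and 0, 0.0039), fibroblast (2.26, 16 and 2, 0.0074) and BMP and TGFb (1.24, 8 and 1, 0.0328). With an estimated correlation their adjusted p was 0.487 to 0.494. Adjusted over each list alone, the calls changed to 0 and 0 for general, 0 and 2 for methylation, 1 and 4 for Wnt targets, 17 and 2 for fibroblast and 9 and 1 for BMP and TGFb, and were the same for the other lists. Of all genes 3425 were called, 2752 higher and 673 lower around an all-gene median of 0.41, and 2428 after quantile normalization, 1435 higher and 993 lower. Median centring gave 3269, 1165 higher and 2104 lower, and so turned the balance. The count was 665 with iPSC in 2i and serum alone as reference and 5450 with iPSC with MEFs alone, and 1515 and 2259 without day 32 replicate a or b. Klf4 lost its call without day 32 replicate a (-1.12, adjusted p = 0.0909) and with iPSC in 2i and serum alone. Sox2 turned to 0.06 after quantile normalization and to 0.55 with iPSC with MEFs alone, and to 0.05 and 0.41 without replicate b of iPSC with MEFs or day 32 replicate a. Pou5f1 turned to -0.09 after median centring and to -0.05 with iPSC in 2i and serum alone.

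Most genes that set the day 32 sample apart from iPSC were shifted in the direction of iPSC in the Sox2-positive against the Sox2-negative fraction. Only the sign of the shift was counted. A gene that went beyond its iPSC level also counts, and the distance to iPSC was not measured. Of the 665 genes called between the day 32 sample and iPSC in 2i and serum, 568 (85.4%) were shifted toward iPSC in the positive against the negative fraction, with a median shift of 0.98. Among the 450 genes higher at day 32 the share was 88.0% (396 genes, median 1.23), and among the 215 lower it was 80.0% (172 genes, median 0.52). With the planned iPSC mean as reference 2270 of 3425 genes (66.3%) were shifted that way, with a median of 0.29 and r = 0.53 across genes. Genes are not independent replicates, and single omissions gave 62.4% to 77.9%. Without day 32 replicate b the median was 0.58 and r 0.68, and without replicate a r was 0.39. Between comparisons whose groups share no array, 281 genes were higher both at day 32 against iPSC in 2i and serum and in the Sox2-negative fraction against iPSC with MEFs, where independent lists would share 53.8. For the Sox2-positive fraction the number was 86, against 27.6. For lower genes the shared numbers were 141 (76.5 for independent lists) and 85 (64.0) in the same order. All calls took the spread of a gene from the same fit over all arrays, so genes with a small spread are favoured in both comparisons. The numbers for independent lists are therefore no strict baseline.

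The comparisons of each fraction with the day 32 sample cross the array classes, and most genes were called lower in the fractions. In the Sox2-positive fraction Cd2ap was 76.4-fold higher (limma adjusted p = 1.27e-05), Myo10 69.1-fold, the linker histone gene H1f4 57.7-fold and Kdm5c at least 47-fold, and Mgst1 was at least 74.8-fold lower, Krt6b at least 59.5-fold, Calcrl at least 32.2-fold and Prss23 at least 22.9-fold. In the Sox2-negative fraction H1f4 was 100-fold higher, the hedgehog receptor gene Smo at least 67.9-fold (adjusted p = 1.30e-05), Ammecr1 at least 38.2-fold and Slc7a1 at least 19-fold, and Sox2 was 198-fold lower, Zfp42 at least 155-fold, Dner at least 137-fold and Trap1a at least 42.4-fold. Another kept probe set of Cd2ap and of Kdm5c in the positive fraction, and of Smo in the negative, differed in the opposite direction. Sox2 was 1.97 lower in the positive fraction (0.0015), and Klf4 and Myc were 2.04 (0.0080) and 3.29 (0.0118) higher in the negative. The other differences were -0.05 and -0.11 for Pou5f1 in the positive and the negative fraction (0.9056 and 0.7775), and 1.33 for Klf4 (0.0513) and 1.83 for Myc (0.1119) in the positive. Limma called 6263 genes for the positive fraction (422 higher and 5841 lower, all-gene median -1.46) and 6404 for the negative (428 and 5976, -1.47). Quantile normalization left 4019 (1348 higher and 2671 lower) and 4126 (1329 and 2797), and median centring 3835 (2469 and 1366) and 3728 (2344 and 1384). Camera placed ribosomal genes above the other genes in both (median 0.22, mean -0.03, 4 higher and 2 lower, adjusted p = 2.64e-05 in the positive, and median 0.07, mean -0.18, 1 and 2, 4.59e-04 in the negative), though Rps6 was 12.5-fold and 14.2-fold lower. It did the same in the positive fraction for the general (median -0.12, 2 and 4, 0.0033) and naive lists (median -0.30, 1 and 3, 0.0060, with Pecam1 7.09-fold higher), and in the negative for the ERK response (median -0.51, 2 and 5, 0.0264, with Etv5 21.5-fold higher and Spry1 at least 2.09-fold lower). These medians lay 0.96 to 1.67 above the all-gene medians, and the adjusted p was 0.831 with an estimated correlation in the positive fraction and 0.942 in the negative. Over each list alone, higher and lower calls were 0 and 1 for ribosomal genes in both, 1 and 2 for general, 1 and 3 for naive and 2 and 5 for ERK. Sox2 in the positive fraction was -0.29 after median centring (adjusted p = 0.5598), Klf4 in the negative turned to -0.98 with the mean of its probe sets and lost its call without day 32 replicate a (1.13, 0.0531), and Myc lost it without Sox2-negative replicate b (2.85, 0.0646). Pou5f1 turned to 0.77 and 0.72 after quantile normalization and to 1.62 and 1.54 after median centring, and to 0.22 without Sox2-positive replicate b and 0.41 without Sox2-negative replicate a. Myc in the positive fraction passed after quantile normalization (3.16, 0.0218).

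The 2 iPSC groups also differ by array class, and iPSC in 2i and serum had low ERK response and immediate early genes. The ERK feedback gene Spry4 was 6.70-fold lower in iPSC in 2i and serum (limma adjusted p = 0.0047), Egr1 6.54-fold, Etv5 25.8-fold (5.59 ± 0.23 against 10.28 ± 0.06, n = 2, 2.07e-05), Fos 22.2-fold (2.35e-04), Zfp36 16.5-fold (1.76e-04), Fosb at least 6.92-fold and Hspa1a at least 5.1-fold. The largest rises were Psap (at least 61.2-fold, adjusted p = 2.07e-05), Hebp1 (49.5-fold), Rpl39l (at least 43.9-fold), Slc15a1 (40.4-fold), Cdc37l1 (40.2-fold), Scamp2 (at least 36.8-fold), Tgfbi (at least 24.3-fold) and Retreg3 (at least 19.8-fold). The largest falls were Smo (at least 62.5-fold, 1.94e-05), Cd2ap (56.5-fold), Myo10 (53.3-fold), Mid1 (36.4-fold), H1f4 (at least 34.8-fold), Crkl (at least 30.7-fold), Kmt2d (at least 21.9-fold) and Rptn (at least 16.6-fold). Smo, Kmt2d, Cd2ap, Crkl, H1f4, Mid1, Myo10 and Etv5 were low on every array with low 18S and high on every array with high 18S, so their differences follow the array class. This holds for the probe set used, and another kept probe set of Smo, of Cd2ap and of Cdc37l1 differed in the opposite direction between the iPSC groups. Pou5f1 and Sox2 were 1.12 (0.0226) and 1.13 (0.0302) higher in 2i and serum and Myc 3.06 lower (0.0209), while Klf4 differed by -0.55 (0.4041). Limma called 5253 genes, 4552 higher and 701 lower, around an all-gene median of 1.0. After quantile normalization there were 3136, 1861 higher and 1275 lower, and after median centring 3833, 1311 higher and 2522 lower. The ERK response (14 genes, median -0.52, 1 higher and 6 lower, camera adjusted p = 4.56e-05) and immediate early lists (17 genes, -0.38, 3 and 8, 4.56e-05) passed as lower. So did ribosomal genes (14 genes, -0.52, 3 and 6, 1.80e-04, with Rpsa 2.75-fold lower), and glycolysis (15 genes, median -0.32, mean 0.15, 4 and 1, 0.0346, with Pfkm 6.70-fold higher), each relative to the risen all-gene median. With an estimated correlation the adjusted p was 0.238, 0.270, 0.810 and 0.810 in that order. Adjusted over each list alone only glycolysis changed, to 3 and 1. Pou5f1 and Sox2 lost their calls on leaving out any of the 4 iPSC arrays (0.0611 to 0.1118 and 0.0744 to 0.1368), and turned to -0.12 and -0.11 after median centring. Myc lost its call without iPSC in 2i and serum replicate a (-1.71, 0.1621) and without replicate a or b of iPSC with MEFs (0.0816 and 0.0837). Spry4 moved from -2.74 to -1.59 without iPSC in 2i and serum replicate a, and Egr1 from -2.71 to -1.33 without its replicate b. Egr1 lost its call without replicate a of iPSC with MEFs (0.0698).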

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

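All tests of this part were chosen only after the result was seen. The 18S control probe set was 6.76 log2 units higher on the 6 arrays of iPSC with MEFs and the sorted fractions than on the 4 arrays of iPSC in 2i and serum and the day 32 sample. The labels do not tell which amplification kit each sample had, and no sample group lies in both classes.

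The difference over most genes between these classes may stem from amplification or processing. If so, the difference between the 2 iPSC groups should resemble the difference between the day 32 sample and its fractions, which shares no array with it. Across 8599 genes the correlation of the 2 differences was r = 0.71, above the value of 0.5 set for this explanation. Culture of iPSC in 2i as the whole cause should leave under 60% of genes on the same side of the median in both, and the share was 73.6%, which excludes it as the whole cause. Genes are not independent replicates, and sorting and culture could still add to the difference. Kit assignments per sample, or spike-in RNA added before amplification, would settle it.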

How the results depend on the processing

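The alternatives tied to the added comparisons, whose single iPSC references had been planned only as alternatives, and the choice of genes called against iPSC in 2i and serum alone, were chosen only after the result was seen. With 2 arrays per group, leaving out an array leaves a lone sample that is assumed to vary like the other groups. The number of genes called stayed within 1.5-fold in 96 of 111 settings of the planned comparisons and 19 of 29 of the added ones, and of 313 named-gene results that passed 197 kept their call in every setting. Whether the replicate letters pair samples is not stated, and they were not used as pairs. Deviations of replicates correlated by 0.33 and 0.21 between the day 32 sample and its positive and negative fraction, by 0.05 between the fractions and by -0.06 to 0.04 elsewhere. With the letters as a replicate block 1180 genes were called between the fractions, 6287 and 6443 for the positive and negative fraction against the day 32 sample, 5430, 5900 and 3426 for the positive fraction, the negative fraction and the day 32 sample against iPSC, and 5254 between the iPSC groups. The replicate block gave 3068 and 4061 genes for the fractions against iPSC with MEFs, 756 for day 32 against iPSC in 2i and serum, and 41 list calls.

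Counts moved by more than 1.5-fold as follows, and the cause was not tested unless stated. Between the fractions array weights gave 369 genes, the compared arrays alone 323, and single omissions 404 to 1052. For the positive fraction against day 32, quantile normalization gave 4019 and median centring 3835, and for the negative fraction 4126 and 3728, since centring removes the all-gene shift. For the positive fraction against iPSC these were 2970 and 2964, and 3088 with iPSC with MEFs alone. The day 32 sample against iPSC gave 665 and 5450 with iPSC in 2i and serum or iPSC with MEFs alone, and 1515 to 2845 over omissions. The iPSC groups gave 3136 after quantile normalization. Against iPSC with MEFs the positive fraction gave 1594 after quantile normalization and 1192 to 2672 over omissions, and the negative fraction 2523 to 3536. Day 32 against iPSC in 2i and serum gave 262 with the compared arrays alone and 127 to 696 over omissions.

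Of 189 list tests in the planned comparisons camera called 37, and 0 with an estimated correlation (smallest adjusted p = 0.238), while fry called 110 and kept 16 of the 37. Fry gave the opposite direction to camera for 6 list results, none of which passed with fry (adjusted p = 0.2065 to 0.8949). Camera compares with the other genes and fry does not, but the cause of the reversals was not tested. For BMP and TGFb and for glycolysis the list median had the sign that camera gave. The glycolysis mean had the opposite sign, and the all-gene medians of these 2 comparisons were -0.97 and 1. The sign of the list median therefore does not decide whether a shift of all genes accounts for these reversals. The list medians were -0.30 (naive) and -0.12 (general) for the positive fraction against day 32, -0.51 (ERK response) and 0.07 (ribosomal) for the negative fraction against day 32, 0.33 (BMP and TGFb) for the negative fraction against iPSC, and -0.32 (glycolysis) between the iPSC groups. The share of genes shifted toward iPSC, 66.3% (SD 2.9 over 4 array pairs), was 69.9% for genes at least 2-fold changed, 70.7% after quantile normalization, 85.4% for genes called against iPSC in 2i and serum alone, and 62.4% to 77.9% over omissions.

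Differences that turned sign were these, and the cause was not tested beyond the removed all-gene shift. Klf4 between the fractions was 1.70 with the mean of probe sets. For the positive fraction against day 32, Pou5f1 was 0.77 after quantile normalization and 1.62 after median centring, Zfp42 0.05, Fbxo15 0.04 and Rps14 0.80 after median centring, and Rps24 -0.69 without probe sets whose names end in s_at, x_at or a_at. For the negative fraction against day 32, Klf4 was -0.98 and Spry2 0.06 with the mean of probe sets, Rps24 -1.10 without probe sets of these endings, Pou5f1 0.72 and 1.54 after quantile normalization and median centring, and Rps14 0.86 after median centring. For the positive fraction against iPSC, Klf4 was 0.29 and 0.38 and Sparc 0.12 and 0.44 after quantile normalization and median centring, Sparc 0.01 and Myc -1.28 with iPSC with MEFs alone, and Pou5f1 -0.10 with iPSC in 2i and serum alone. For the negative fraction against iPSC, Klf4 was -3.09 with the mean of probe sets and -0.27 with iPSC with MEFs alone, Sparc 0.22 after median centring, and Pou5f1 -0.16 and Tgfbi -0.10 with iPSC in 2i and serum alone. For day 32 against iPSC, Sox2 was 0.06 after quantile normalization and 0.55 with iPSC with MEFs alone, where Notum was 0.48, Pou5f1 -0.09 after median centring, and Pou5f1 -0.05, Dppa3 0.29 and Bub1 -0.18 with iPSC in 2i and serum alone. Between the iPSC groups, Pou5f1 was -0.12 and Sox2 -0.11 after median centring. Klf4 in the negative fraction against iPSC with MEFs was 0.48 after quantile normalization and 0.17 after median centring, and Pou5f1 at day 32 against iPSC in 2i and serum 0.09 after quantile normalization.

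Single omissions turned the sign as follows, from lowest to highest. Pou5f1 ran from -0.46 to 0.59 between the fractions, -0.32 to 0.22 and -0.64 to 0.41 for the positive and negative fraction against day 32, and -0.13 to 0.92 for the negative fraction against iPSC. Myc ran from -1.15 to 1.64 for the positive fraction against iPSC, -2.67 to 0.12 and -0.25 to 0.62 for the positive and negative fraction against iPSC with MEFs, and -1.39 to 1.29 for day 32 against iPSC in 2i and serum. Klf4 ran from -0.22 to 0.24 for the negative fraction against iPSC, and Sox2 from -0.43 to 0.41 for day 32 against iPSC.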

Other observations

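The tests of the hypotheses in this part were chosen only after the results were seen, and the genes of the first paragraphs were picked after their values were seen. Fosl1, an AP-1 gene of mesenchymal cells, was at least 17.7-fold lower in the Sox2-positive than in the Sox2-negative fraction (limma adjusted p = 4.74e-04), and was 4.24 log2 units higher in the negative fraction than in iPSC with MEFs (2.09e-04) and at least 10.4-fold higher at day 32 than in iPSC in 2i and serum (0.0018). B2m, the light chain of MHC class I, was 3.52 higher in Sox2-negative cells than in iPSC with MEFs (1.57e-04), 1.84 higher in Sox2-positive cells (0.0033), and differed by -1.68 between positive and negative cells (0.0115). The Wnt target Sp5 was at least 8-fold lower in positive and in negative cells than in iPSC with MEFs (8.47e-04 and 9.85e-05).

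Zic1 and Tfap2a, transcription factors that act in the neural crest, were higher in Sox2-negative cells than in iPSC with MEFs. Zic1 was at least 15.7-fold higher (limma adjusted p = 3.66e-04) and Tfap2a at least 41.6-fold higher (4.10e-04), and between the positive and the negative fraction they differed by -3.42 (0.0198) and -3.76 (0.0182). The maternally expressed RNA gene Rian was at least 1.45-fold higher in positive than in negative cells (0.0083) and at least 1.8-fold lower in negative cells than in iPSC with MEFs (0.0011). Replicates differed in places. Dazl read 5.96 and 9.33 on the day 32 arrays, Pkp1 7.21 and 1.22 on the Sox2-positive arrays, and Acta2 2.71 and 8.03 on the arrays of iPSC in 2i and serum.

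Pou5f1 stood at nearly the same level in both fractions although most pluripotency genes did not. Sox2-positive cells left in the negative fraction were excluded as the cause, since the pluripotency genes other than the Yamanaka factors kept a median of only 4.05% of their positive level, where carry-over would need a large share. Pou5f1 itself kept 95.6%. The median is approximate, as some of these genes were under the filter value of 4 in the negative fraction, such as Zfp42 (2.87) and Dppa2 (2.92). A ceiling of the Pou5f1 probe set stays open, since only 4 pluripotency genes were as bright (median difference 3.66) and probe sets may level off at different values. RNA of the introduced factors could keep Pou5f1 high, and the gap between the Klf4 probe sets changed by -6.20 in the negative fraction relative to iPSC. Probe positions were not used here, so the gap cannot decide. The day 32 sample showed a gap close to that of iPSC. Its arrays belong to the other array class than the fractions, so its gap weighs neither for nor against this explanation. Reads or probes that separate endogenous from introduced transcripts would decide.

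Genes higher in Sox2-positive cells than in iPSC with MEFs might come from Sox2-negative cells in the sort, and this stays open. Of the 527 genes 310 had a higher mean in the positive than in the negative fraction, 86 of them called, such as Slc11a1 (9.80 against 3.39), which such cells would not bring, while 42 were called lower, such as Pax3 and Foxd1. When the genes were chosen without Sox2-positive replicate a or b and read on the array left out, 15.5% and 8.0% lay at least 2-fold above every Sox2-negative and iPSC with MEFs array, against 4.7% and 6.8% between the Sox2-negative arrays, an excess of only 1.2 points for replicate b. Among 13 genes bright in the negative fraction and dim in iPSC with MEFs, replicate a kept a median of 20.2% of the negative level and replicate b 1.69%, but the share was uneven, with 1.11% for Fabp4, 0.151% for Krt6b and 6.07% for Krtdap in replicate a and 80.8% for Tgfbi in replicate b.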
